A study of Tetranychus urticae with 12 samples.

How the data were processed

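Whole-body RNA was measured by paired-end mRNA sequencing in untreated mites of 3 strains of Tetranychus urticae, a plant-feeding spider mite, per the labels. The strains were Trizina, described by the labels as resistant to many compounds, and London and BC2018-14, described as susceptible. The labels gave 4 libraries per strain and 12 in all. The mites were kept on kidney bean without exposure to insecticides, and the library kit kept the strand of the RNA, per the labels' protocols.

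The authors deposited a table of raw read counts per gene for 19114 gene IDs. The tools used, per the submitters' processing notes, were the aligner HISAT2 2.1.0, SAMtools 1.10, the read counter featureCounts 1.6.0 and edgeR, and the notes used here give no order or settings. The version of edgeR, the genome build, the annotation and the strand setting of the counting were not given in the sources used here. Overlapping genes, antisense pairs and near-identical copies are therefore uncertain, and no coordinates are given. The authors also deposited 2 comparison tables, of Trizina against London and of Trizina against BC2018-14, with log2 fold changes and p-values or false discovery rates per the file headers, beside the counts of the libraries compared.

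The header of the raw count table named 12 libraries, whereas each line held 11 values. The 11 columns were assigned to libraries because their values equalled the named count columns of the comparison tables at every gene listed there. This was 1458 of 1458 genes for the Trizina libraries and for London libraries 2, 3 and 4, and 967 of 967 genes for the Trizina and BC2018-14 libraries. No column of the raw table held London library 5. Its counts were used for the genes of the deposited Trizina and London table and for nothing else. The genome-wide fit therefore had 11 libraries, with 3 of London, 4 of BC2018-14 and 4 of Trizina, where the design fixed in advance had assumed 12.

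The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14394, and libraries were scaled with TMM factors. A quasi-likelihood model with robust dispersion and strain as its only term was fitted to the 11 libraries together, and the 3 pairs of strains were contrasts of that fit. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its absolute log2 fold change was at least 1. Standard errors are of the log2 fold change. Levels are given as CPM, the usual scaling of counts to a fixed total, computed on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Fitted log2 fold changes used the default prior count of the edgeR fit instead. Where every library of a strain had 0 counts, a fold is given as a bound, computed against 3 counts in each library of that strain, or about 0.104 CPM in London, 0.106 in BC2018-14 and 0.105 in Trizina. Where a strain had 1 to 3 counts in all, the ratio is given with an exact 95% interval for counting error. Limits and intervals of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

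Total counts per library ran from 26090006 to 39875401. The same steps were tested on counts simulated from the means of 14394 genes and the library sizes, with 200 genes changed in each of 3 simulations. The filter left 14199 genes on average. Changed genes had a mean of at least 1 CPM, so the shares called do not cover rarer genes. Changes of 1.5 on the log2 scale were called in 88% of cases between Trizina and London and in 90.3% between Trizina and BC2018-14. For changes of 3 on the log2 scale these shares were 97.7% and 98.7%. False calls made up 1.42% and 1.22% of all calls in the 2 comparisons. No pair of libraries of a strain agreed within sampling noise, with chi-square per degree of freedom from 6.99 to 157. The labels do not say that the libraries of a strain came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

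The tests, thresholds, gene lists and the rule for naming genes were fixed before the data were examined. By that rule the named genes were those with the largest fitted log2 fold change in each direction among called genes with no overlap between the libraries of the 2 strains and a mean of at least 10 CPM in the higher strain. For genes called against both susceptible strains the smaller of the 2 changes was ranked, without the condition on overlap. The files do not pair gene IDs with names, and 0 of the 19114 IDs matched the table of 14930 RefSeq genes, so at most 2 IDs are printed per direction and comparison. The planned lists of detoxification, transport, target-site, cuticle, yolk and other genes were to be matched on gene descriptions and could not be applied, and neither could their set tests. Numbers of genes called in a single strain against both others, genes on and off, runs of neighbouring IDs and variation within strains were examined only after the values had been seen.

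Alternatives were DESeq2 size factors, upper-quartile factors or library size alone as scaling, DESeq2 1.42.0 and limma-voom (limma 3.58.1) as tests, no filter or a filter of 5 CPM in 4 libraries, other thresholds, fits of 2 strains at a time, removal of each library in turn, and removal of genes under 1 CPM in Trizina. Chance was examined by refitting other splits of the same libraries and by simulating unchanged Trizina libraries that shared both comparisons. Figures were drawn with matplotlib 3.10.9.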

Results

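Gene expression was compared between whole mites of the multi-resistant Trizina strain of Tetranychus urticae and those of 2 susceptible strains, London and BC2018-14, all untreated. The question set by this design was which transcripts differ between the resistant strain and each susceptible strain without exposure to a compound. Trizina was the only resistant strain, so differences tied to resistance cannot be told apart from other differences of that strain. Genome-wide counts were used for 4 Trizina, 4 BC2018-14 and 3 London libraries. Total counts per library ran from 26454588 to 30799433 in Trizina, from 26090006 to 26851943 in BC2018-14 and from 29262202 to 39875401 in London. Between 15334 and 16171 genes had a count in a library, and 14394 genes were tested.

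The 3 strains were clearly separated in expression. Across genes, log2 CPM correlated at 0.973 to 0.994 between libraries of the same strain. It correlated at 0.926 to 0.946 between Trizina and BC2018-14, at 0.874 to 0.901 between Trizina and London and at 0.848 to 0.889 between the susceptible strains. The first principal component, with 56.8% of the variance, set London apart, and the second component, with 28.3%, separated Trizina from BC2018-14. The London libraries varied more than the others, with a median SD of 0.255 log2 CPM (n = 3), against 0.151 in Trizina (n = 4) and 0.139 in BC2018-14 (n = 4). Of the genes tested, 4300 (29.9%) were called in at least 1 of the 3 comparisons.

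**Figure D1:**
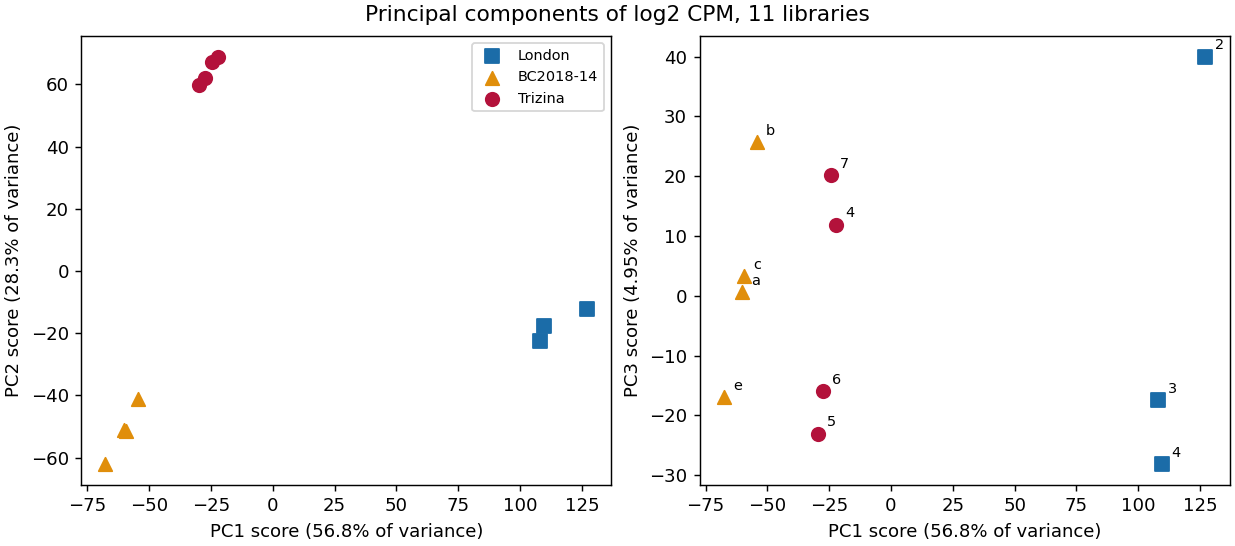
Principal component scores of log2 CPM for the 11 libraries, with 1 point per library, coloured by strain. Component 1 (56.8% of the variance) sets London apart, component 2 (28.3%) separates Trizina from BC2018-14, and component 3 (4.95%) spreads the libraries within each strain.

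Against London, 1097 genes were higher and 1434 genes were lower in Trizina. With genes at 0 counts set to their limit, the median change of the higher genes was 3.98-fold and that of the lower genes 4.49-fold. Some genes were read in Trizina and not at all in London. The gene tetur11g00950 had 39.7 ± 2.39 CPM in Trizina (SD, n = 4) and 0 counts in every London library, so that it was at least 383-fold higher in Trizina. For tetur06g01300, with 35.7 ± 5.15 CPM in Trizina (SD, n = 4) and 0 counts in London, the difference was at least 344-fold. BC2018-14 also expressed these genes, at 15.9 ± 0.977 and 17.2 ± 1.43 CPM (SD, n = 4).

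In the other direction, tetur30g01850 reached 2266 ± 664 CPM in London (SD, n = 3) and had 0 counts in every Trizina library, at least 21600-fold lower. The gene tetur30g90547, at 165.0 ± 30.8 CPM in London (SD, n = 3), also had 0 counts in Trizina and was at least 1570-fold lower. BC2018-14 had 0.390 ± 0.189 CPM of it (SD, n = 4) and was also called lower than London. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 4 genes had adjusted p of 4.86e-10, 3.19e-09, 1.57e-05 and 7.43e-08. Among genes with at least 100 CPM in either strain, 39 were higher and 119 lower in Trizina, of 2783 tested. The majority of lower genes depended on scaling and filtering. With TMM factors 43.3% of called genes were higher in Trizina, against 51.5% with library size alone, which moved the median of all genes by 0.17 on the log2 scale. The majority also turned with a filter of 5 CPM in 4 libraries (506 higher, 460 lower) and without genes under 1 CPM in Trizina (880 higher, 684 lower). The first filter removes genes read in London alone, since London has 3 libraries, and the second removes genes low in Trizina. Both therefore take out lower genes by construction.

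Against BC2018-14, the direction was the opposite, with 1426 genes higher and 746 genes lower in Trizina. The median change, with genes at 0 counts set to their limit, was 3.36-fold for the higher genes and 3.01-fold for the lower genes. The gene tetur09g06240 had 46.9 ± 1.1 CPM in Trizina (SD, n = 4) and 0 counts in BC2018-14, at least 442-fold higher. London had 1.69 ± 0.360 CPM of it (SD, n = 3), a log2 difference of 4.78 ± 0.164 (SE) from Trizina. The gene tetur09g01060, at 37.4 ± 6.85 CPM in Trizina (SD, n = 4) and 0 counts in BC2018-14, was at least 353-fold higher. London had 1.65 ± 0.498 CPM of it (SD, n = 3).

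The 2 genes with the largest fitted decrease from BC2018-14, a rank that depends on the prior count of the fit, had 0 counts in Trizina. For tetur20g00030, BC2018-14 had 23.7 ± 14.5 CPM (SD, n = 4), so that Trizina was at least 226-fold lower, although the BC2018-14 libraries differed widely. For tetur641g00010, at 11.98 ± 0.865 CPM in BC2018-14 (SD, n = 4), Trizina was at least 114-fold lower. London had only 1.62 ± 0.284 CPM of it (SD, n = 3), and BC2018-14 was called higher than London. The adjusted p of the 4 genes against BC2018-14 were 9.54e-09, 1.36e-07, 0.000185 and 6.26e-08 (edgeR quasi-likelihood, Benjamini-Hochberg). Among genes with at least 100 CPM in either strain, 98 were higher and 29 lower in Trizina, of 2737 tested. The share of higher genes was 65.7%, and this majority rested on the minimum fold change, since adjusted p alone (edgeR quasi-likelihood, Benjamini-Hochberg) gave 2869 higher and 2830 lower genes, or 50.3% higher.

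Against both susceptible strains, 397 genes were higher and 318 genes were lower in Trizina. The smaller of the 2 changes had a median of 3.36-fold for the higher genes and 3.12-fold for the lower genes, with genes at 0 counts set to their limit. Of the higher genes, 251 had no call between London and BC2018-14, and of the lower genes, 201 had none. Calls between these 2 strains covered 21.7% of all tested genes, a smaller share than among the higher or the lower genes. With adjusted p alone and no minimum fold change the balance turned, to 916 higher and 959 lower genes (edgeR quasi-likelihood, Benjamini-Hochberg). The gene tetur05g07590 had 28.3 ± 0.870 CPM in Trizina (SD, n = 4) and 0 counts in every library of both susceptible strains. It was at least 273-fold above London and at least 267-fold above BC2018-14. The gene tetur39g90795 had the same distribution at 10.3 ± 0.392 CPM in Trizina (SD, n = 4), at least 99.3-fold above London and at least 97.1-fold above BC2018-14.

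Among the genes lower in Trizina than in both, tetur20g00030 had 0 counts in Trizina and 16.2 ± 8.00 CPM in London (SD, n = 3), at least 155-fold lower than in London. The gene tetur27g02160 had 17.0 ± 3.21 CPM in London (SD, n = 3), 22.3 ± 1.59 CPM in BC2018-14 (SD, n = 4) and 3 counts over the 4 Trizina libraries. The ratio of London to Trizina was 641, with an exact 95% counting interval of 219 to 3110, and that of BC2018-14 to Trizina was 853, with an interval of 292 to 4140. Adjusted p for tetur27g02160 was 4.01e-09 against London and 4.97e-09 against BC2018-14 (edgeR quasi-likelihood, Benjamini-Hochberg). For tetur20g00030 the same test gave 0.000222 and 0.000185, for tetur05g07590 2.21e-07 and 1.89e-07, and for tetur39g90795 1.42e-06 and 1.24e-06.

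Independent lists of these lengths would share 109 higher and 74.3 lower genes. The overlap was 3.65 times the independent number for higher and 4.28 times for lower genes. The same ratios were 5.1 and 7.41 for London apart from both others, and 5.48 and 4.24 for BC2018-14, so such an overlap was not particular to Trizina. Unchanged Trizina libraries simulated against both strains shared 0 calls in each of 20 simulations, which held no changes to share and so set no level for the overlap of real changes. With the Trizina libraries split so that each comparison used a separate pair, 566 to 617 genes were called in both over the 6 splits. Fold changes of Trizina over the 2 strains had a covariance of 0.562 across genes, against 0.0354 in the simulations, a difference of 0.527. The simulations held no strain differences, and any difference of Trizina from both strains raises the covariance above them. The correlation of the fold changes across genes was 0.245, against 0.461 from shared libraries alone, and genes are not independent replicates.

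A further 260 genes were called in both comparisons in opposite directions. Of these, 209 were lower in Trizina than in London and higher than in BC2018-14, and 51 showed the reverse. Of the 1556 genes called against London but not against BC2018-14, 1224 (78.7%) also differed between the susceptible strains. The corresponding number for BC2018-14 was 802 of 1197 genes (67%). Among all tested genes 21.7% were called between the susceptible strains. That contrast is the difference of the 2 Trizina contrasts, so genes called in only 1 of them tend to differ there by construction. The 3 comparisons share libraries and are not independent.

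**Figure D2:**
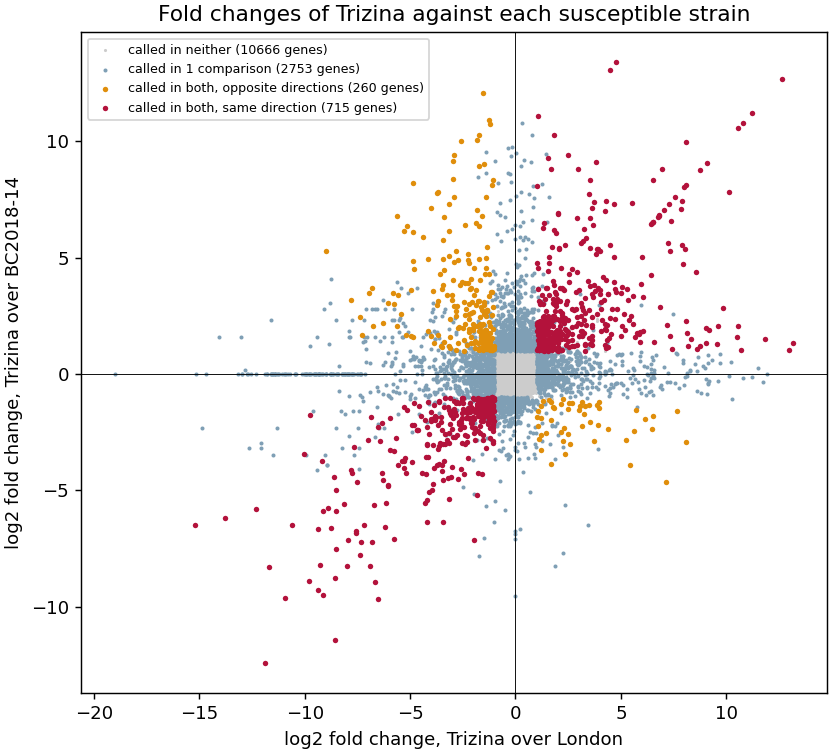
Fitted log2 fold change of each tested gene in Trizina over London (horizontal) and over BC2018-14 (vertical), with 1 point per gene, coloured by the calls in the 2 comparisons. Values of genes with 0 counts in a strain depend on the prior count of the fit. The 715 genes called in the same direction lie in the upper right and lower left, and the 260 called in opposite directions in the other corners.

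Between the susceptible strains, which measure strain differences not tied to Trizina, 1105 genes were higher and 2016 genes were lower in BC2018-14 than in London. The median change was 3.49-fold for the higher and 4.47-fold for the lower genes, with genes at 0 counts set to their limit. The genes tetur11g00990 and tetur11g00980 had 18.8 ± 1.47 and 17.3 ± 1.65 CPM in BC2018-14 (SD, n = 4) and 0 counts in London, at least 181-fold and 167-fold higher. Trizina expressed them too, at 14.9 ± 1.35 and 17.1 ± 2.08 CPM (SD, n = 4). The 2 genes and tetur11g00950 lay in 1 run of 11 neighbouring IDs called higher in BC2018-14 than in London. In the other direction, tetur30g01850 had 0 counts in BC2018-14 as in Trizina, at least 21400-fold below London. The gene tetur18g03040 had 228.1 ± 62.6 CPM in London (SD, n = 3), 0 counts in BC2018-14, at least 2150-fold lower, and 1 count over the 4 Trizina libraries. Adjusted p of these 4 genes between the susceptible strains were 2.22e-09, 4.9e-09, 1.26e-05 and 5.02e-08 (edgeR quasi-likelihood, Benjamini-Hochberg). With library size alone 1581 genes were higher and 1698 lower, a share of 48.2% higher against 35.4% with TMM factors, and the median of all genes moved by 0.248 on the log2 scale. Adjusted p alone gave 3264 higher and 3511 lower genes, also 48.2% higher (edgeR quasi-likelihood, Benjamini-Hochberg).

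**Figure D3:**
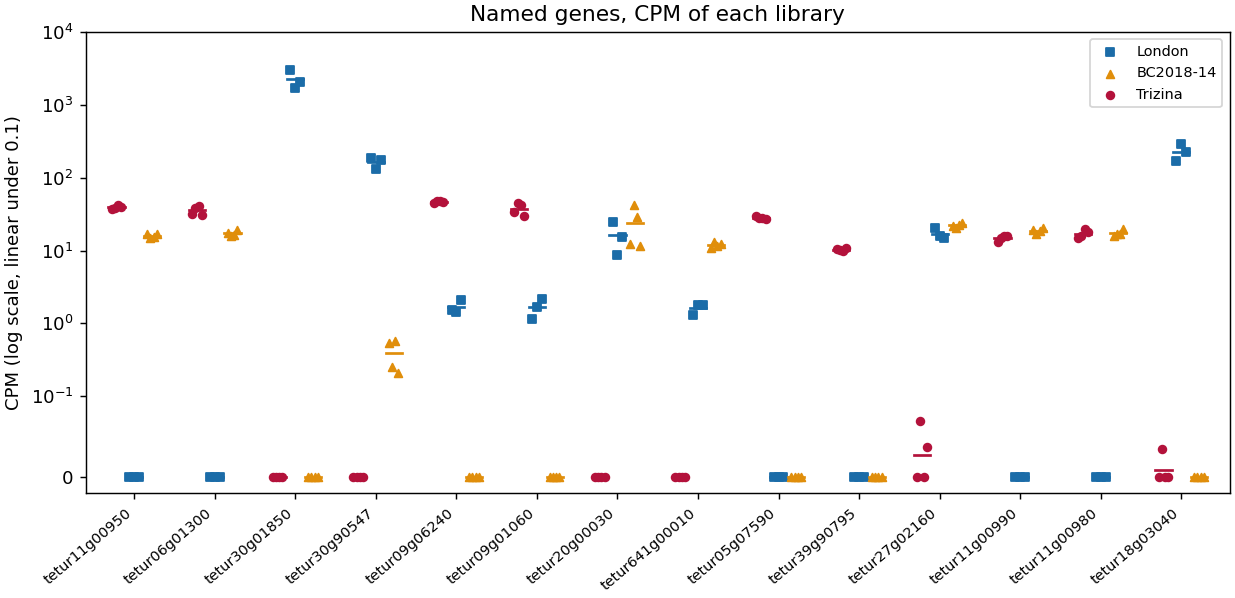
CPM of each library for the 14 named genes, on a log scale that is linear below 0.1 CPM, with 1 point per library and a line at the mean of each strain. The gene tetur30g01850 had 2266 CPM in London and 0 counts in the other strains, and tetur05g07590 was read in Trizina only, at 28.3 CPM.

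London differed from both other strains in the same direction for 1649 genes, BC2018-14 for 1160 genes and Trizina for 715 genes. This order depended on the filter, since 5 CPM in 4 libraries gave 570 genes for London and 591 for BC2018-14. London was higher than both for 1025 genes and lower than both for 624 genes. The majority of higher genes ended with a filter of 5 CPM in 4 libraries (279 higher, 291 lower), which removes genes read in London alone. It also ended without genes under 1 CPM in Trizina (462 higher, 505 lower), which removes genes low in Trizina. Both filters thus take out genes higher in London by construction. Among genes with a mean of at least 1 CPM in every strain, TMM factors gave 368 higher and 230 lower, and library size alone 293 and 327. At a mean of at least 5 CPM in every strain, TMM factors gave 178 higher and 85 lower. BC2018-14 was higher than both other strains for 314 genes and lower than both for 846 genes, a split that was 1536 higher and 1658 lower with adjusted p alone (edgeR quasi-likelihood, Benjamini-Hochberg). With on defined as at least 5 CPM in every library and off as at most 3 counts in every library, 41 genes were on in London and off in both other strains, and 16 genes were off in London and on in both. Trizina had 2 genes on alone, tetur05g07590 and tetur39g90795, and 2 genes off alone, tetur20g00030 and tetur27g02160. BC2018-14 had 1 gene on alone and 5 genes off alone. With on as at least 1 CPM these numbers were 108 on and 51 off for London, 11 and 10 for Trizina, and 3 and 37 for BC2018-14. These definitions were set after the values had been seen.

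A few abundant genes took a larger part of the London libraries. Of the 10 genes with the highest mean CPM in London, a set chosen after the values had been seen, 4 were called higher there than in both other strains, by 2.31-fold to 9.87-fold over Trizina and by 6.6-fold to 35.5-fold over BC2018-14. The highest adjusted p among them was 0.029 against Trizina and 0.00063 against BC2018-14 (edgeR quasi-likelihood, Benjamini-Hochberg). Together they held 9.53 ± 1.9% of all counts in London (SD, n = 3), 2.59 ± 0.39% in Trizina (SD, n = 4) and 1.12 ± 0.64% in BC2018-14 (SD, n = 4). Of the 4 genes, 3 were also called higher in Trizina than in BC2018-14. TMM factors were 0.874 to 0.918 in London, 1 to 1.025 in Trizina and 1.055 to 1.089 in BC2018-14.

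The authors' deposited table of Trizina against London listed 1458 genes, 593 higher and 865 lower in Trizina. The authors' deposited table of Trizina against BC2018-14 listed 967 genes, 662 higher and 305 lower. By their values, the authors' deposited tables held genes with a false discovery rate below 0.001 and an absolute log2 fold change of at least 1.5. Of the London table, 1450 genes were tested here, each with the same sign, and 1448 were called. Of the BC2018-14 table, 967 were tested, each with the same sign, and 965 were called. Log2 fold changes differed from those in the authors' deposited tables by a median of 0.0647 for London and 0.0111 for BC2018-14. At the thresholds of the deposited tables, the fit of 11 libraries gave 1268 genes against London, 1160 of them listed, and 787 genes against BC2018-14, 707 of them listed. The authors' deposited tables shared 374 genes, of which 180 were higher and 113 lower in Trizina in both.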

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

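The definition of genes on and off and the examination of opposite directions were chosen after the results had been seen. Among the named genes and library measures, 26 groups of 4 libraries were checked for a library far from the others, and 1 was found, where chance gives about 1 in 20. It was tetur18g03040 in Trizina, where 1 library had 0.0347 CPM, a single read, and the other 3 had 0, so that the gap to the nearest library was the whole range, a ratio of 1. A single read is below the limit of 3 counts.

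The effect of Trizina changed direction with the susceptible strain for 260 genes. Genes chosen in this way differ between BC2018-14 and London by construction, so that contrast adds no test, and the difference was not tested in other libraries. Of these genes, 209 lay below London and above BC2018-14, and 51 the reverse.

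Other splits of the same libraries were refitted to see whether chance could give as many calls. For Trizina and London, 1 of 35 splits of the 7 libraries, the real one, gave 2439 calls, and the highest of the other splits gave 0. For Trizina and BC2018-14, 1 of 35 splits of the 8 libraries gave 2007 calls and the highest other gave 0. For BC2018-14 and London, 1 of 35 splits gave 2888 calls and the highest other gave 1. Of 60 drawn splits of the 11 libraries, 1, the real one, gave 715 genes called against both strains in the same direction, and the highest other gave 0. The other splits mixed libraries of clearly separated strains, which widens the spread within groups and leaves few calls to find. They show that the calls followed the strains. They set no level for differences between cultures of 1 strain.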

How the results depend on the processing

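Added after the results had been seen were the thresholds of the deposited tables, library sizes without 4 abundant London genes, variation within strains as a covariate, the definitions of on and off and the counts of London and BC2018-14 apart from both others. Counts are given in the order Trizina against London, Trizina against BC2018-14, BC2018-14 against London, both Trizina comparisons, London apart from both others and BC2018-14 apart from both others, with 2531, 2172, 3121, 715, 1649 and 1160 genes as reported. A filter of 5 CPM in 4 libraries gave 966, 1028, 1378, 302, 570 and 591, with fewer genes tested, and it removes genes read in London alone because London has 3 libraries. Adjusted p alone gave 5254, 5699, 6775, 1875, 3349 and 3194. A test against 2-fold (glmTreat) gave 1580, 963, 1935, 329, 1065 and 490. The thresholds of the deposited tables gave 1268, 787, 1539, 243, 872 and 370. These last 3 differ by the construction of the threshold. With adjusted p alone the majority of higher genes in both Trizina comparisons turned (916 higher, 959 lower). Leaving out genes under 1 CPM in Trizina gave 1564 against London, 446 in both Trizina comparisons and 967 for London apart, since it removes genes low in Trizina. The other alternatives, including DESeq2 (2837, 2447, 3530 and 791 for the first 4 counts) and limma-voom (2512, 2227, 3127 and 736), stayed within 1.5 times of the reported counts.

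Leaving out each of 11 libraries in turn gave 2375 to 2611, 1928 to 2321, 2962 to 3219, 632 to 743, 1561 to 1712 and 1016 to 1277 genes. The named genes kept their direction and call in 481 of 481 combinations of gene, comparison and alternative in which they were tested. They had been picked for the largest changes in the same data, so this is weak support. Alternatives that changed only a threshold, or left out genes after the fit, reused the reported fit, so direction could not change there. With adjusted p alone no call could be lost either. Filters that dropped a named gene, such as tetur30g01850 at 5 CPM in 4 libraries, are not among the 481. With off as 0 counts, London had 25 genes on and 8 off alone, BC2018-14 0 and 3, and Trizina 2 and 1. With on as 10 CPM these were 26 and 7, 1 and 3, and 1 and 1, and with on as 1 CPM 108 and 51, 3 and 37, and 11 and 10. No paired analysis was possible because London and Trizina shared only replicate number 4 among the 11 libraries, and the BC2018-14 libraries carry letters. The planned gene lists with camera, fry and list medians, and the planned replicate block, were not run. Genes under about 0.1 CPM could not be compared at this depth.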

Other observations

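The patterns in this part were first seen in the data. The test of library sizes without the 4 abundant genes, the scalings and the block interval for genes of at least 1 CPM in every strain and the covariate for variation within strains were chosen only after results had been seen. Genes that differed between strains lay next to each other in the list of gene IDs more often than in a random order, although most had no such neighbour. A neighbour called in the same direction was found for 37.6% of called genes against London, 32.7% against BC2018-14, 41.7% between the susceptible strains and 18.7% of the 715 genes called against both strains. Against London, 585 pairs of neighbouring tested IDs were called in the same direction, where 10000 random orders of the IDs gave 222 on average and 273 at most. The longest run of neighbouring IDs called in 1 direction held 12 genes, higher in Trizina, with tetur11g00950, tetur11g00980 and tetur11g00990 among them. Against BC2018-14 there were 422 such pairs (random mean 176), and between the susceptible strains 781 (random mean 360).

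For genes called against both susceptible strains in the same direction, 79 neighbouring pairs were found, where random orders gave 17.5 on average and 36 at most, which argues against a chance order of IDs. The ratio to the random mean was 2.64, 2.40 and 2.17 in the 3 comparisons, the lowest being 2.17, which argues against differences spread evenly over the list. A candidate explanation is that neighbouring IDs are copies or share a local difference between strains. Reads shared between near-identical copies were not tested and stay open, and the files do not give coordinates.

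London was above both other strains more often than below, with 1025 against 624 genes (62.2% higher, exact binomial 95% interval 59.8 to 64.5). Composition scaling may account for part of it: over other scalings the lowest share was 53.3% (50.9 to 55.7), with library size alone, between the bounds of 50 and 55 set before the test, so this stays open. With the 4 abundant London genes left out of the library sizes the share was 58.5% (56 to 60.8), which does not decide it. For near-absence in the other strains the answer depended on scaling. Among genes of at least 1 CPM in every strain the share was 61.5% with TMM factors (57.1 to 65.9 over resampled blocks of 50 neighbouring IDs). It was 62.3% (57.8 to 66.8) with DESeq2 size factors and 60.2% (55.7 to 64.5) with upper-quartile factors, but 47.3% (42.7 to 51.9) with library size alone. The bounds set before the test named no scaling. A share of 50% or less was to go with near-absence, and a share above 50% by more than its exact binomial interval against it. With TMM factors the bound against near-absence was met (57.5 to 65.5). With library size alone the bound for it was met (47.3%, exact interval 43.3 to 51.3). The scalings thus gave opposite answers, and near-absence stays open. For genes near 0, 2.56 times as many were on in London alone as off in London alone, as predicted if reads of the other strains aligned poorly to a London-derived reference, but gene loss and a true strain difference predict the same and the build was not given in the sources used here.

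Libraries also varied within strains, along a leading axis that held 34.9% of the variance within strains. The leading axes of the 3 strains correlated across genes at a mean absolute r of 0.336 (0.243, 0.363 and 0.402), above the highest of 20 simulations with independent noise (0.023), but these carried no co-expression of genes, so whether each strain varied separately stays open. Sequencing depth stays open over the 11 libraries: Pearson's r of strain-centred scores with log2 total counts was -0.417 (permutation p = 0.517), Spearman's rho was -0.518 (permutation p = 0.231), and r was 0.145 without the 2 farthest libraries. Differences in age, stage or sex make-up between the samples of mites could give variation of this kind and were not tested. With this axis as a covariate 763 genes were called in both Trizina comparisons, against 715 without it. The axis was taken from the same libraries after strain means were removed, so it takes up spread within strains by construction. The larger number is therefore no support for the calls.

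For the 1450 genes of the deposited Trizina and London table that were tested, London library 5, which was outside the genome-wide fit, lay on the London side for 1449 (99.9%). It correlated with the other London libraries at 0.971 to 0.990 across these genes. These genes had been selected by the authors with that library included, so they are not an independent check.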
